A study of Mus musculus with 20 samples.

How the data were processed

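The series holds RNA sequencing of mouse muscle endothelial cells, the cells that line the blood vessels of skeletal muscle. Per the labels, cells with CD31 and without CD45 on their surface were sorted from the soleus, an oxidative muscle, or from the extensor digitorum longus, a glycolytic muscle, of C57BL/6N mice. The mice were either wild type or lacked Atf4 in endothelial cells (Atf4 ECKO). Deletion was induced by 1 mg tamoxifen per day over 5 days and followed by at least 7 days without treatment, and the wild type mice were littermates without Cre that received the same tamoxifen. The 20 libraries fall into 4 groups of 5. They were made with a stranded, poly(A)-selecting kit and sequenced from 1 end. The labels give neither the number of animals behind a library nor what the replicate numbers pair. The p-values therefore measure only the spread between these libraries, which may be technical.

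The authors deposited 1 table per library with estimated counts per transcript and transcript abundances in TPM. The submitters' processing notes name kallisto for these values and DESeq2 for testing, without versions, and they give the genome build as GRCh38.p13, a human assembly. The transcript identifiers are those of mouse Ensembl transcripts, and 128643 of them, 128254 with identical length, were found in the mouse GENCODE release M21 on GRCm38, so this annotation was used for gene names and all coordinates. The deposited TPM values and effective lengths were not used for the main tests, and effective lengths entered 1 alternative. Strand handling in the authors' quantification is not given in the sources used here. Genes that overlap another gene or have near-identical copies are therefore called uncertain where they are named.

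Estimated counts were summed over the transcripts of each gene, giving 42374 genes, and rounded to whole numbers. At most 0.221% of a library's counts lay in transcripts without a match. Library totals ranged from 8013223 to 21720127 counts. The gene CT010467.1 took between 8.91% and 12.2% of the counts of every library. Levels are given as CPM, counts per library scaled to a common total, with TMM-normalised library sizes. A gene with 0 counts in all libraries of a group was set against a floor of 3 counts over the group, which covers counting error only.

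Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the low-count filter filterByExpr, all 20 libraries in 1 fit of group means, and Benjamini-Hochberg adjustment. In all, 13971 genes were tested and an adjusted p below 0.05 was a call. The SE given with a gene's log2 value is the size of that value over the square root of the test's F statistic. It rests on the spread of all 20 libraries and is approximate, above all for genes near 0 counts in a group. The 5 comparisons were oxidative against glycolytic muscle in each genotype, Atf4 ECKO against wild type in each muscle, and the interaction, which tests whether the effect of genotype differs between the muscles. Of 35 gene lists, 34 had the minimum of 3 tested members. They were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and Benjamini-Hochberg adjustment over the lists of a comparison. The adipocyte list had 1 tested gene and was left out. Camera with an estimated correlation and the rotation test fry were run as alternatives. Mean log2 fold changes of lists in the main fit are means over tested members of the edgeR estimates. In fits with a covariate or with part of the libraries they are means of voom estimates unless edgeR is named. Main and alternative means are therefore not on exactly the same scale. Levels of Atf4 and Atf3 were also compared by 2-sided exact permutation tests over the 252 assignments of 10 libraries.

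The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text could name Atf4 and Atf3, then for each comparison up to 10 genes with the largest rise and 10 with the largest fall among called genes with a mean of at least 4 CPM, an ordinary gene symbol and no place on a list of another cell type, and up to 4 members with the smallest adjusted p of each list described. The text takes part of the genes the rule gives, picked after their values had been seen. Rps19bp1 in oxidative muscle, Cyp26b1 in oxidative muscle, Tnfsf4, Mief1 and the sex-specific genes lie outside the rule and were chosen after their values were seen.

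The alternatives were RLE factors, no low-count filter, DESeq2 1.42.0, limma-voom, an offset for transcript length, a fit of the compared groups alone, the replicate number as a block, the level of muscle fibre genes or the share of Y-linked RNA as a covariate, and leaving out each library in turn. After seeing the data, further alternatives were added: the level of immune genes as a covariate, the oxidative Atf4 ECKO libraries with or without Y-linked RNA alone, autosomal and mitochondrial genes alone, and the oxidative wild type libraries without those highest in fibroblast RNA.

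The procedure was tested on simulated counts of 13742 genes with changes planted for 3 comparisons, 66 genes at each size of change. For oxidative against glycolytic wild type, 63.6% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 95.5% of those changed 4-fold were called, and 11 of the 187 calls were unchanged genes. For Atf4 ECKO against wild type in oxidative muscle the shares were 65.2%, 75.8% and 93.9%, with 11 unchanged genes among 184 calls. For the interaction they were 42.4%, 72.7% and 90.9%, with 7 unchanged genes among 159 calls. In the other comparisons, where nothing was planted, 0 genes were called. In the comparisons with planted changes the list raised in the simulation passed and 0 of the other lists did. Simulated genes were drawn independently of each other, so the simulation could not test the preset correlation among members of a list. Libraries of a group were compared pairwise by chi-square tests, and every pair differed beyond sampling noise, at 475 to 4669 genes. Libraries made from the same cells can differ in this way too, so these differences do not show separate animals. Figures were drawn with matplotlib 3.10.9.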

Results

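RNA was sequenced from endothelial cells (CD31-positive, CD45-negative) of the oxidative soleus and the glycolytic extensor digitorum longus of wild type mice and of mice that lack Atf4 in endothelial cells. Each of the 4 groups held 5 libraries. The biological coefficient of variation within groups was 8.17% in glycolytic wild type, 10.1% in oxidative wild type, 6.83% in glycolytic Atf4 ECKO and 13.4% in oxidative Atf4 ECKO. The first principal component, with 28.3% of the variance, set oxidative wild type apart from the other groups, and the second, with 17.2%, set glycolytic wild type apart.

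Atf4, a transcription factor of the integrated stress response that drives genes of amino acid supply (ENSMUSG00000042406.8, chromosome 15, 80255184 to 80257541, plus strand, GRCm38), stood at 262 CPM ± 13.5 (SD, n = 5) in glycolytic and 554 CPM ± 21 in oxidative wild type endothelium. In Atf4 ECKO it stood at 7.38 CPM ± 0.996 in glycolytic and 8.29 CPM ± 0.351 in oxidative muscle, or 2.82% and 1.5% of the wild type level of the same muscle. The deletion was present in each of the 10 ECKO libraries, whose highest Atf4 level was 8.7 CPM against a lowest wild type level of 243 CPM. Atf3, a related stress-induced transcription factor (ENSMUSG00000026628.13, chromosome 1, 191170296 to 191218039, minus strand), stood at 327 CPM ± 64.1 in oxidative wild type, 76.6 CPM ± 2.56 in glycolytic wild type, 83.5 CPM ± 5.08 in oxidative ECKO and 66.5 CPM ± 3.07 in glycolytic ECKO. Exact permutation p was 0.0079, the smallest that 5 against 5 libraries allow, for both genes in all comparisons of muscle within genotype and genotype within muscle, except Atf4 between the muscles in ECKO (exact permutation p = 0.063).

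**Figure D1:**
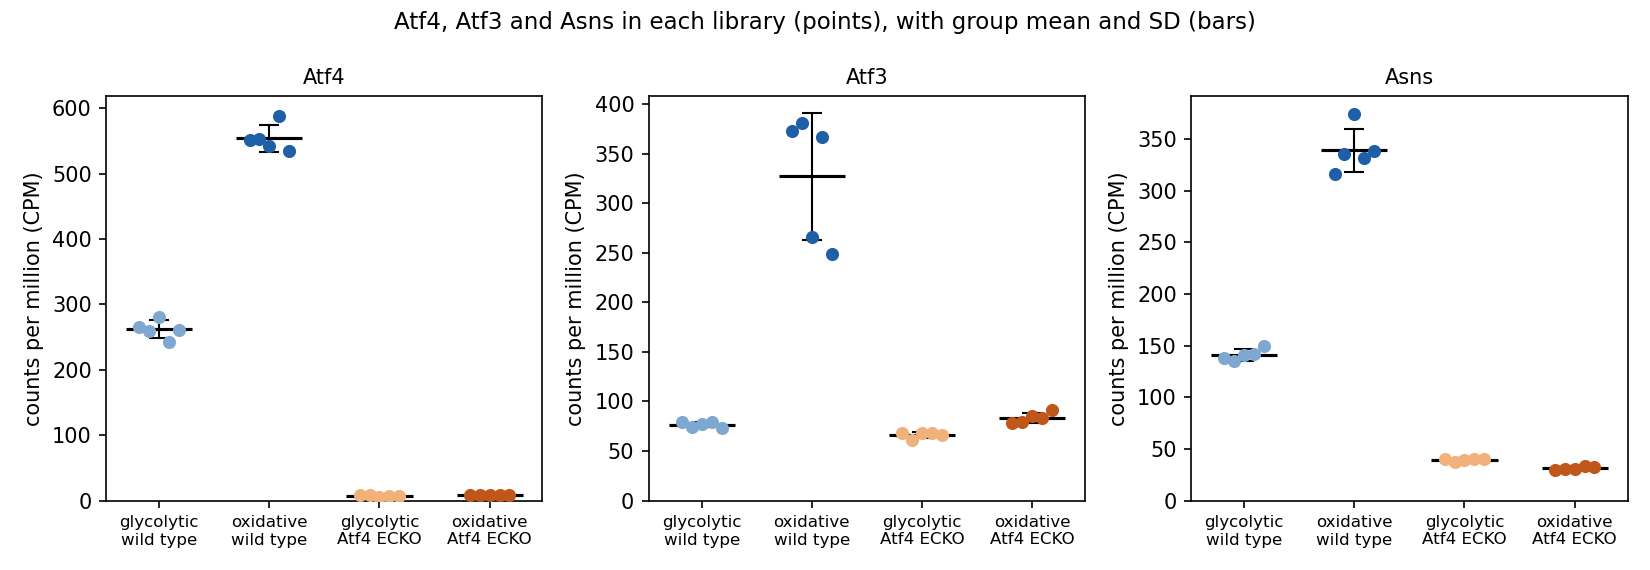
Levels of Atf4, Atf3 and the asparagine synthetase gene Asns in CPM (vertical axes) in the 5 libraries of each group (points), with the group mean (line) and SD (bars). Atf4 lies between 535 and 589 CPM in oxidative wild type, between 243 and 281 CPM in glycolytic wild type and at or below 8.7 CPM in every ECKO library.

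RNA of other cells and sex-specific RNA moved with the groups. Xist, the X-inactivation transcript of female cells, was at most 0.274 CPM in the 10 wild type libraries, which carried Y-linked RNA (Ddx3y, Uty, Kdm5d and Eif2s3y together 95.1 CPM ± 3.84 in glycolytic and 114 CPM ± 4.69 in oxidative muscle, SD, n = 5). The glycolytic ECKO libraries held 61.4 CPM ± 2.85 Xist and at most 1.62% of the wild type level of Y-linked RNA. Oxidative ECKO libraries 4 and 5 likewise held 0.817% and 0.961% of it, while libraries 1, 2 and 3 carried both kinds of RNA, with 56.6%, 57.5% and 28.2% of the wild type Y-linked level. The wild type comparison of muscles is thus matched for sex, and the comparisons of genotype are not. Lyz2, a macrophage and granulocyte lysozyme, stood at 185 CPM ± 19.9 in oxidative wild type, 9.54 CPM ± 1.24 in glycolytic wild type, 47.3 CPM ± 12.7 in oxidative ECKO and 8.47 CPM ± 0.835 in glycolytic ECKO, although CD45-positive cells had been excluded by the sort. Pecam1, which encodes CD31, stood at 1583, 1790, 1861 and 1433 CPM in the same groups. Col1a1, a fibroblast collagen, ranged from 13.8 to 109 CPM among the oxidative ECKO libraries and from 24.8 to 90.6 CPM among oxidative wild type.

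**Figure D2:**
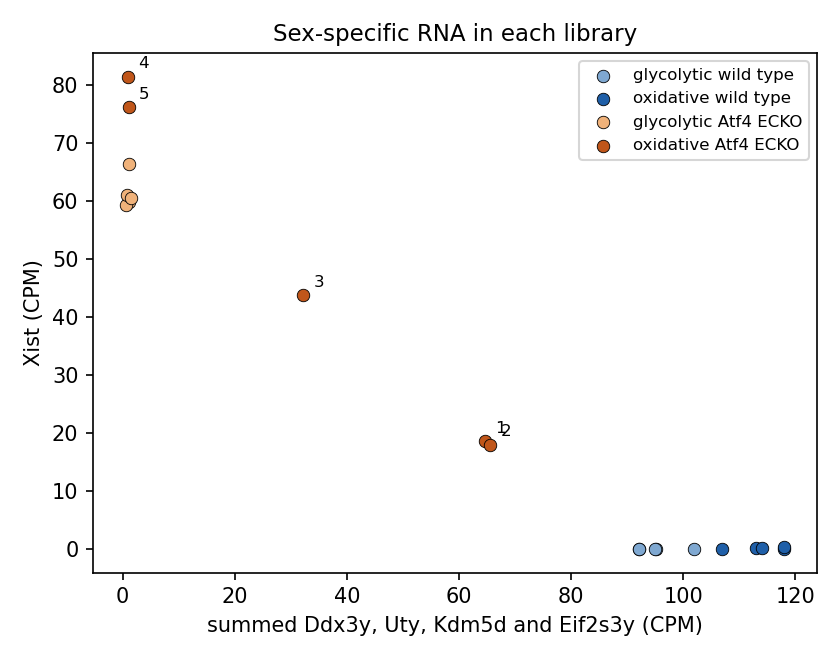
Xist (vertical axis, CPM) against the sum of 4 Y-linked genes (horizontal axis, CPM) in each of the 20 libraries, coloured by group, with replicate numbers for oxidative Atf4 ECKO. Wild type libraries lie at the lower right, glycolytic ECKO and oxidative ECKO 4 and 5 at the left, and oxidative ECKO 1, 2 and 3 in between.

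The study's title concerns endothelial cells that carry ATF3 and ATF4, and the wild type comparison asks how endothelium of the oxidative muscle differs from that of the glycolytic muscle. In oxidative wild type, enzymes that make amino acids and feed the one-carbon pathway were higher as a group. Of the 16 members 15 rose and the other did not pass (mean log2 fold change 1.61). Phgdh, which opens serine synthesis, rose from 25.2 to 123 CPM (log2 fold change 2.29 ± 0.095, SE, n = 5 per group). Mthfd2, a mitochondrial folate enzyme, rose by 1.86 ± 0.068, Shmt2, which moves carbon from serine to folate, by 1.73 ± 0.086, and Asns by 1.26 ± 0.046. Amino acid transporters rose in 12 of 15 members and fell in 0 (mean 1.08). Among them were the glycine transporter Slc6a9 (1.93 ± 0.12), the cystine transporter Slc7a11 (1.40 ± 0.095) and the cationic transporter Slc7a1 (1.21 ± 0.056). Cytosolic tRNA synthetases, which charge tRNAs with amino acids, rose in 14 of 20 members and fell in 1 (mean 0.58). Rars (1.33 ± 0.06) and Gars (1.23 ± 0.054) were among those that rose. Regulators of the stress response rose in 16 of 18 members and fell in 1 (mean 1.34). Among them were the secreted factor Gdf15 (2.62 ± 0.076), Atf3 (2.09 ± 0.09), Ppp1r15a, which helps to end translational arrest (1.91 ± 0.046), and the pseudokinase Trib3 (1.49 ± 0.074). The counts of called members adjusted over the list alone were 15, 12, 15 and 17 for these lists. Camera adjusted p was 1e-23, 3.5e-13, 5.1e-14 and 6.6e-19 with the preset correlation, and 9.4e-05, 0.00057, 0.0021 and 5.5e-05 with an estimated correlation. Below, the second camera p, marked estimated, is the one with an estimated correlation.

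Immediate early genes, which respond to growth signals and to handling, rose in 22 of 26 members in oxidative wild type (mean log2 fold change 1.05, 24 called adjusted over the list alone, camera adjusted p = 2e-19, and 0.0027 estimated). Fos rose by 2.35 ± 0.077 (SE, n = 5 per group) to 1089 CPM and Fosb by 2.92 ± 0.096. The chemokine genes Cxcl1 (2.77 ± 0.093) and Ccl2 (2.65 ± 0.16) and the cytokine gene Il6 (2.46 ± 0.27) rose within the endothelial activation list. Of its 9 members 6 rose and 1 fell (8 called adjusted over the list alone, camera adjusted p = 0.0009, and 0.042 estimated). Hmox1, which breaks down heme, rose from 156 to 1621 CPM (3.38 ± 0.09). Its oxidative stress list rose in 6 of 11 members and fell in 3, Nqo1 among them (-0.71 ± 0.057). That list had 9 members called adjusted over the list alone and a camera adjusted p = 0.0017, but adjusted p = 0.13 with an estimated correlation. Genes of sprouting and tip cells rose in 10 of 15 members and fell in 2 (12 called adjusted over the list alone, camera adjusted p = 0.0017, and 0.016 estimated). The growth factor gene Pgf rose by 1.91 ± 0.12, while Plvap, which forms the diaphragms of fenestrae and caveolae, fell (-1.04 ± 0.045). Cholesterol synthesis fell in 16 of 19 members and rose in 0 (mean -0.57, 18 called adjusted over the list alone, camera adjusted p = 2.1e-10, and 5.5e-05 estimated). Falls included Sqle, which oxidises squalene (-1.04 ± 0.13), and the isoprenoid enzyme gene Fdps (-0.81 ± 0.085). Venous markers fell in 7 of 9 members and rose in 1 (mean -0.49, 9 called adjusted over the list alone, camera adjusted p = 2.5e-06, and 0.00066 estimated). Among them were Lrg1 (-1.62 ± 0.12), Vwf, the von Willebrand factor gene (-0.85 ± 0.052), and the chemokine-binding receptor gene Ackr1 (-0.75 ± 0.066). Pan-endothelial markers also fell in 9 of 16 members and rose in 2 (mean -0.15, 12 called adjusted over the list alone, camera adjusted p = 0.002, and 0.02 estimated).

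Transcripts of other cells were higher in the same oxidative wild type libraries. The immune list rose in 14 of 15 members (mean log2 fold change 3.32, 15 called adjusted over the list alone, camera adjusted p = 2.5e-15, and 0.0049 estimated). The myeloid adaptor gene Tyrobp stood at 20.6 against 0.682 CPM and the complement gene C1qb at 18.1 against 0.632 CPM. Rises outside that list included Ccl6 (8.28 ± 0.34, SE, n = 5 per group), Gpnmb (6.75 ± 0.16), Saa3 (6.61 ± 0.24), the cathepsin gene Ctss (5.59 ± 0.21) and the leukocyte gene Cd53 (5.45 ± 0.27), which myeloid cells also make. Muscle fibre genes rose in 13 of 18 members (median 1.57, 14 called adjusted over the list alone, camera adjusted p = 3e-07, and 0.041 estimated). Myoglobin, Mb, stood at 13.2 against 1.26 CPM. Slow fibre genes rose in 7 of 10 members and fell in 1 (8 called adjusted over the list alone, camera adjusted p = 0.00029 but adjusted p = 0.051 with an estimated correlation). The myosin light chain gene Myl3 stood at 5.48 against 0.0305 CPM. Fibroblast genes rose in 11 of 12 members (11 called adjusted over the list alone, camera adjusted p = 0.0011 but adjusted p = 0.28 with an estimated correlation), Col1a1 by 2.52 ± 0.44. Mitochondrially encoded genes rose in all 13 members (mean 1.31, 13 called adjusted over the list alone, camera adjusted p = 3.5e-19, and 0.031 estimated). The cytochrome oxidase gene mt-Co1 stood at 31066 against 12325 CPM, and mitochondrial transcripts made up 11.4% to 14.2% of counts in oxidative against 5.74% to 6.15% in glycolytic wild type libraries. Falls included Spon2, a matrix protein gene (16 to 1.83 CPM, -3.13 ± 0.22), the cell adhesion gene Kirrel3 (-1.79 ± 0.2) and the synaptotagmin gene Syt15 (-1.67 ± 0.14). Exosc6, at 0 counts in oxidative wild type and 4.56 CPM ± 3.29 in glycolytic, lies within the span of Aars on the same strand and is uncertain.

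In total 4520 of 13971 genes differed between the muscles in wild type (edgeR, adjusted p below 0.05), 2295 higher and 2225 lower in oxidative muscle, and 629 of the higher and 121 of the lower ones changed at least 2-fold. With the preset correlation 28 of 34 lists passed, and 16 of them also did with an estimated correlation. With the level of immune genes as a covariate, 1140 genes were called and the amino acid synthesis list passed with a mean log2 fold change of 1.15 (adjusted p = 0.00026). Stress regulators passed with 0.72 (adjusted p = 0.0032), immediate early genes with 1.69, fibre genes with 2.30 and fibroblast genes with 6.02. With that covariate the amino acid transporters no longer passed (mean 0.01, adjusted p = 0.36), nor did the tRNA synthetases (mean 0.19, adjusted p = 0.14), endothelial activation (mean 0.64, adjusted p = 0.54), venous markers (mean -0.42, adjusted p = 0.081), mitochondrially encoded genes (mean 0.17, adjusted p = 0.52) and the immune list itself (mean 0.09, adjusted p = 0.81). The oxidative stress list turned to -0.13 and the sprouting list to -0.23. The immune level did not overlap between these groups (mean log2 CPM 3.24 to 3.75 in oxidative and 0.36 to 0.65 in glycolytic wild type). The slope thus comes from differences within groups and is extrapolated. A call lost with this covariate therefore does not assign a list to immune RNA. With the level of muscle fibre genes as a covariate, 1259 genes were called and the fibroblast list turned to -1.72. Mitochondrially encoded genes then had a mean of 2.11 and slow fibre genes 1.59, and the fibre list itself no longer passed (mean 0.13, adjusted p = 0.65). The fibre level did not overlap between these groups either (mean log2 CPM 1.84 to 2.44 in oxidative and 0.63 to 0.87 in glycolytic wild type). Its slope is thus extrapolated too, and the turn of the fibroblast list rests on it. A list's own level as a covariate takes out its change by construction, here and below, so such outcomes are no test.

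**Figure D3:**
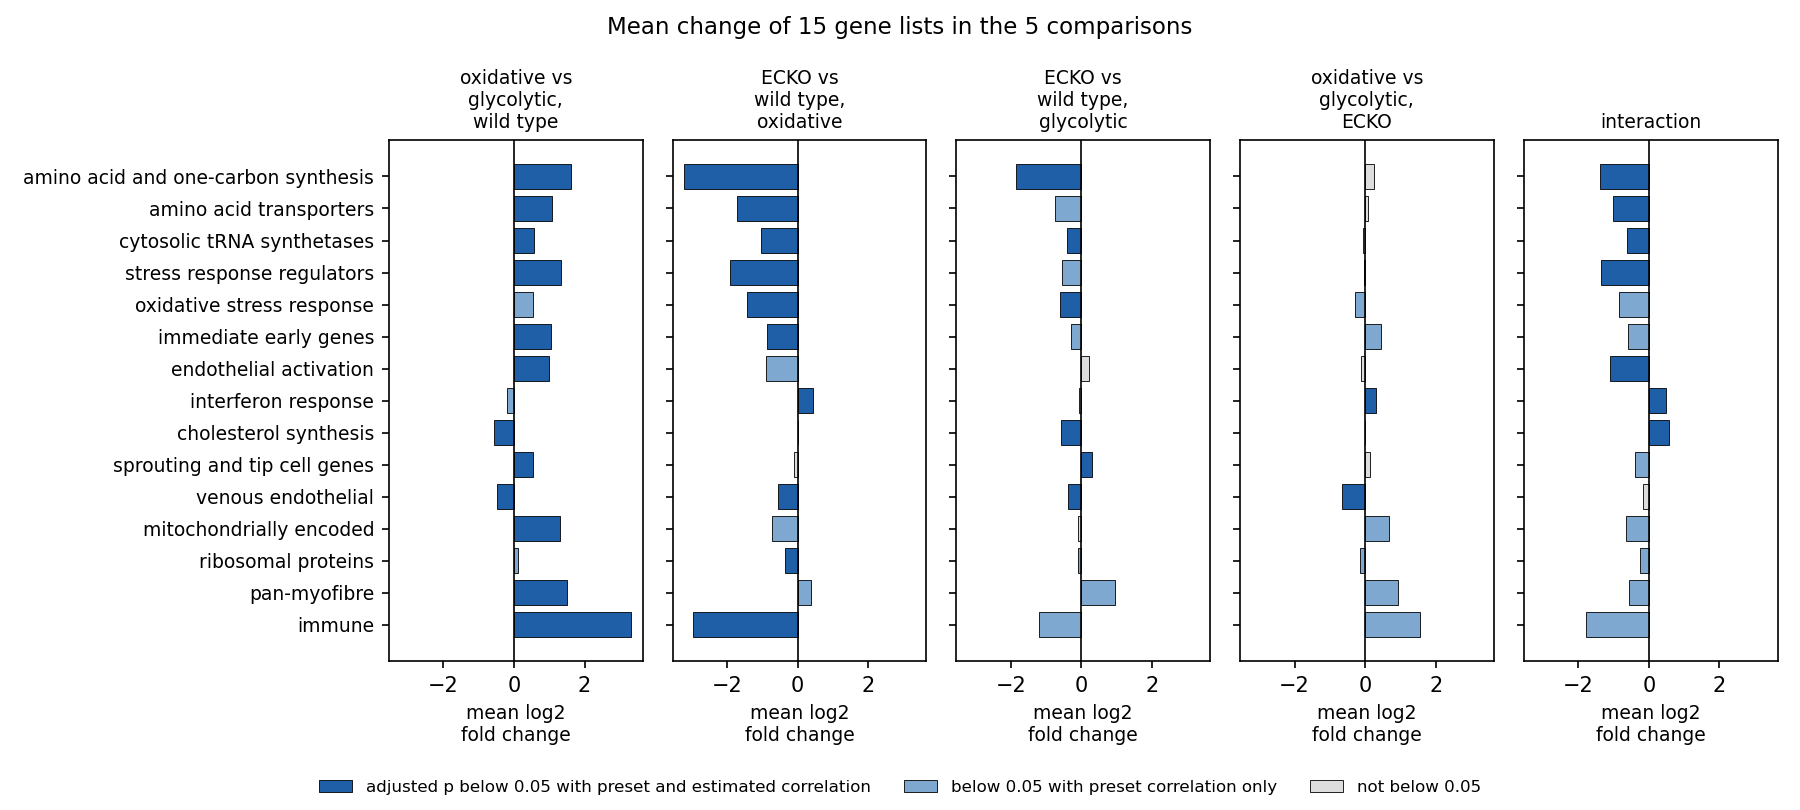
Mean log2 fold change (horizontal axes) of the tested members of 15 gene lists in the 5 comparisons (panels), coloured by whether the list's camera test passed with the preset and the estimated correlation. The amino acid synthesis list lies at 1.61 between the muscles in wild type, at -3.22 and -1.85 for ECKO against wild type in oxidative and glycolytic muscle, and at 0.25 between the muscles in ECKO, where its test did not pass.

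The comparison of Atf4 ECKO with wild type in oxidative muscle asks what endothelial cells of the soleus lose without Atf4. Amino acid and one-carbon synthesis fell in 15 of 16 members and rose in 1 (mean log2 fold change -3.22). Mthfd2 dropped from 144 to 4.12 CPM (-5.11 ± 0.09, SE, n = 5 per group) and Phgdh from 123 to 4.41 CPM (-4.84 ± 0.12). Psat1, the next enzyme of serine synthesis, dropped from 156 to 8.38 CPM (-4.23 ± 0.1) and Asns from 339 to 31.3 CPM (-3.43 ± 0.052). Bcat1, which transaminates branched-chain amino acids, dropped to 0.461 CPM (-5.89 ± 0.2). Amino acid transporters fell in 12 of 15 members and rose in 1 (mean -1.73). Slc1a4, a transporter of small neutral amino acids, fell (-4.45 ± 0.2), and so did Slc7a11 (-3.77 ± 0.11). The tRNA synthetases fell in 16 of 20 members and rose in 2 (mean -1.03). Cars had a log2 fold change of -2.20 ± 0.066 and Gars one of -1.95 ± 0.056. Stress regulators fell in 16 of 18 members and rose in 1 (mean -1.91). They included Nupr1, a stress-induced chromatin protein gene (-4.22 ± 0.17), Chac1, which degrades glutathione (-3.73 ± 0.11), Gdf15 (-3.02 ± 0.079) and Trib3 (-2.95 ± 0.083). Called members adjusted over the list alone numbered 16, 13, 18 and 17. Camera adjusted p was 1.1e-25, 4.5e-13, 4.8e-21 and 1.7e-19 with the preset and 9e-05, 0.0014, 0.0014 and 7.5e-05 with an estimated correlation.

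The oxidative stress list fell in 10 of 11 members in oxidative ECKO (mean log2 fold change -1.45, 10 called adjusted over the list alone, camera adjusted p = 8.7e-17, and 0.0041 estimated). Hmox1 dropped from 1621 to 96.5 CPM (-4.07 ± 0.093, SE, n = 5 per group) and Gclm, a subunit of the first enzyme of glutathione synthesis, fell too (-2.15 ± 0.062). Immediate early genes fell in 21 of 26 members and rose in 1 (mean -0.88, 22 called adjusted over the list alone, camera adjusted p = 2.7e-14, and 0.011 estimated). Fosl1 had a log2 fold change of -2.51 ± 0.14 and Fos one of -1.58 ± 0.075. Venous markers fell in 6 of 9 members and rose in 2 (8 called adjusted over the list alone, camera adjusted p = 0.0031, and 0.015 estimated). The leukocyte adhesion gene Selp (-1.75 ± 0.061) and Ackr1 (-1.25 ± 0.071) were among them. In the endothelial activation list 4 of 9 members fell and 2 rose (6 called adjusted over the list alone, mean -0.89, camera adjusted p = 0.015 but adjusted p = 0.2 with an estimated correlation). Cxcl1 (-2.37 ± 0.092) and Il6 (-3.28 ± 0.3) fell. Without oxidative ECKO library 5 the list no longer passed (adjusted p = 0.058). Ribosomal protein genes, which have many processed copies that can share reads, fell in 38 of 40 members by a small amount (mean -0.35, 38 called adjusted over the list alone, camera adjusted p = 6.4e-25, and 0.033 estimated). Rpl4 was among them (-0.58 ± 0.044). Interferon response genes rose in 13 of 17 members (mean 0.43, 13 called adjusted over the list alone, camera adjusted p = 6.9e-10, and 0.0049 estimated). The antiviral Ifit2 rose by 0.71 ± 0.06 and Usp18, which limits interferon signalling, by 0.62 ± 0.058. Ifit3, which has a near-identical copy and is uncertain, rose by 0.98 ± 0.054.

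Beside these groups, the immune list fell in all 15 members in oxidative ECKO (mean log2 fold change -2.97, 15 called adjusted over the list alone, camera adjusted p = 1.5e-16, and 0.0056 estimated). Tyrobp stood at 2 CPM against 20.6 and the antigen presentation gene Cd74 at 0.797 CPM against 13.9. Ccl6 (-6.74 ± 0.3, SE, n = 5 per group) and Saa3 (-4.48 ± 0.2) were among the falls. All 13 mitochondrially encoded genes fell (mean -0.73, 13 called adjusted over the list alone, camera adjusted p = 1.3e-11 but adjusted p = 0.13 with an estimated correlation). Mitochondrial transcripts made up 7.38% to 10.6% of counts. Muscle fibre genes rose in 7 of 18 members (mean 0.39, 7 called adjusted over the list alone, camera adjusted p = 0.01 but adjusted p = 0.31 with an estimated correlation). Pericyte and smooth muscle genes rose in 7 of 13 members (mean 0.32, 7 called adjusted over the list alone, camera adjusted p = 0.0063 but adjusted p = 0.36 with an estimated correlation). Their mean was 0.21 without oxidative ECKO library 5 and 0.22 without oxidative wild type library 4. Rises included Cacna1i, a T-type calcium channel gene (chromosome 15, 80287238 to 80398279), with 15.3 CPM ± 2.04 against 0 counts in every wild type library, at least 339-fold over the floor of 3 counts for the group. Esr1, the estrogen receptor alpha gene, rose from 2.18 to 33.3 CPM (3.94 ± 0.16). Tent5b, which encodes a poly(A) polymerase, rose by 2.19 ± 0.2, the receptor gene Gpr160 by 2.16 ± 0.2 and the transcription factor gene Zbtb16 by 1.74 ± 0.18. Tnfsf18, the ligand of the T cell receptor GITR, dropped from 9.45 to 0.348 CPM (-4.74 ± 0.33).

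In total 4470 genes differed between oxidative ECKO and wild type (edgeR, adjusted p below 0.05), 2035 higher and 2435 lower in ECKO, 161 and 460 of them at least 2-fold. Of 34 lists, 20 passed with the preset correlation and 11 of these also with an estimated one. Sex differed between these groups. With the Y-linked share as a covariate 2643 genes were called, with oxidative ECKO libraries 4 and 5 alone 3808 and with libraries 1, 2 and 3 alone 4349. The amino acid synthesis list had a mean of -3.00, -3.23 and -3.22 in turn. With the covariate, mitochondrially encoded genes (mean -0.07, adjusted p = 0.65), endothelial activation (mean -0.59, adjusted p = 0.73) and venous markers (mean -0.49, adjusted p = 0.051) no longer passed, fibre genes turned to -0.03 and pericyte genes to -0.45, and the immune list had a mean of -1.71. With the level of immune genes as a covariate 1380 genes were called and the amino acid mean was -2.78, but endothelial activation no longer passed (mean -0.57, adjusted p = 0.91) and mitochondrially encoded genes turned to 0.30. Pericyte genes turned to -1.06, a call in the other direction (adjusted p = 0.0081), and fibre genes to -0.32. Transporters passed with -0.76, tRNA synthetases with -0.67, oxidative stress genes with -0.82 and immediate early genes with -1.50, and the immune list itself turned to 0.05. Libraries 4 and 5 alone gave fibre and pericyte genes a mean of 0.64 each. With libraries 1, 2 and 3 alone, endothelial activation (mean -0.80, adjusted p = 0.24), fibre genes (mean 0.29, adjusted p = 0.17) and pericyte genes (mean 0.11, adjusted p = 0.13) no longer passed. Nor did endothelial activation (mean -0.80, adjusted p = 0.098), fibre genes (mean 0.02, adjusted p = 0.59) and pericyte genes (mean 0.05, adjusted p = 0.36) with the level of muscle fibre genes as a covariate.

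The same comparison in glycolytic muscle asks what endothelial cells of the extensor digitorum longus lose without Atf4. Amino acid and one-carbon synthesis fell in 13 of 16 members and rose in 0 (mean log2 fold change -1.85, 14 called adjusted over the list alone, camera adjusted p = 6.3e-14, and 0.0015 estimated). Bcat1 fell (-4.74 ± 0.27, SE, n = 5 per group), as did the proline synthesis gene Pycr1 (-3.44 ± 0.31), Mthfd2 (-3.19 ± 0.098) and Phgdh (-3.06 ± 0.14). Asns fell from 141 to 39.4 CPM (-1.84 ± 0.051). The tRNA synthetases fell in 14 of 20 members and rose in 2 (mean -0.40, 17 called adjusted over the list alone, camera adjusted p = 1.2e-09, and 0.0095 estimated). Cars (-1.07 ± 0.069) and Yars (-0.90 ± 0.068) were among them. Transporters fell in 8 of 15 members and rose in 2 (mean -0.74, 11 called adjusted over the list alone, camera adjusted p = 0.0084 but adjusted p = 0.15 with an estimated correlation). Slc1a4 fell (-2.62 ± 0.2) and Slc38a2, a neutral amino acid transporter, rose (0.65 ± 0.051). Stress regulators fell in 9 of 18 members and rose in 2 (mean -0.54, 11 called adjusted over the list alone, camera adjusted p = 0.0013 but adjusted p = 0.053 with an estimated correlation). Chac1 (-1.78 ± 0.12) and Trib3 (-1.64 ± 0.088) fell. The oxidative stress list fell in 8 of 11 members and rose in 0 (mean -0.61, 10 called adjusted over the list alone, camera adjusted p = 2.3e-09, and 0.011 estimated). Nqo1, a quinone reductase gene, was among them (-1.94 ± 0.062).

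Cholesterol synthesis fell in 16 of 19 members in glycolytic ECKO and rose in 0 (mean log2 fold change -0.57, 16 called adjusted over the list alone, camera adjusted p = 5.1e-11, and 3.7e-05 estimated). The isoprenoid enzyme gene Idi1 fell from 32.9 to 14.6 CPM (-1.17 ± 0.11, SE, n = 5 per group), and the squalene synthase gene Fdft1 fell as well (-0.70 ± 0.085). Sprouting and tip cell genes rose in 8 of 15 members and fell in 2 (mean 0.30, 12 called adjusted over the list alone, camera adjusted p = 0.0014, and 0.0095 estimated). The peptide ligand gene Apln rose by 1.32 ± 0.1, Esm1, a tip cell proteoglycan gene, by 1.17 ± 0.097 and Angpt2, an antagonist of vessel stability, by 1.14 ± 0.082. Arterial markers fell in 8 of 13 members and rose in 0 (mean -0.41, 9 called adjusted over the list alone). Venous markers fell in 7 of 9 and rose in 1 (mean -0.39, 9 called adjusted over the list alone), Selp with -1.01 ± 0.059. Both marker lists had a camera adjusted p of 1.6e-05, and 0.0015 estimated. Pan-endothelial markers fell too, in 8 of 16 members, and rose in 1 (mean -0.18, 10 called adjusted over the list alone, camera adjusted p = 0.00049, and 0.0095 estimated). The smooth muscle actin gene Acta2 rose from 189 to 1024 CPM (2.44 ± 0.095) and the actin-binding gene Tagln from 130 to 519 CPM. The pericyte and smooth muscle list, which holds them, rose in 4 of 13 members and fell in 2 (mean 0.45, 6 called adjusted over the list alone, camera adjusted p = 0.024 but adjusted p = 0.45 with an estimated correlation). Fn1, the fibronectin gene, which fibroblasts also make, rose by 2.37 ± 0.089.

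Beside these groups, muscle fibre genes rose in 12 of 18 members in glycolytic ECKO (mean log2 fold change 0.95, 12 called adjusted over the list alone, camera adjusted p = 0.00012 but adjusted p = 0.14 with an estimated correlation). The skeletal actin gene Acta1 stood at 70.1 against 19.1 CPM. Fibroblast genes rose in 6 of 12 members (mean 1.13, 9 called adjusted over the list alone, camera adjusted p = 0.013 but adjusted p = 0.45 with an estimated correlation), and Col1a1 stood at 21.7 against 8.92 CPM. The immune list fell in 6 of 15 members (7 called adjusted over the list alone, mean -1.20, camera adjusted p = 0.0027 but adjusted p = 0.24 with an estimated correlation). Apart from transcripts of the X-inactivation centre, rises included Cacna1i (19.5 CPM ± 1.37, SD, n = 5, against 0 counts in every wild type library, at least 543-fold over the floor of 3 counts for the group) and Pmaip1, an apoptosis gene (1.64 to 23.5 CPM). Others were Ankrd1, a stretch-responsive gene (15.4 to 205 CPM), Esr1 (2.69 to 29.6 CPM), Tmem171 (4.49 to 39.3 CPM) and the LIM domain gene Fhl2 (5.19 to 43.5 CPM). Falls included Tnfsf18 (9.81 to 0.409 CPM), Rps19bp1, which encodes an activator of the deacetylase SIRT1 and lies beside Atf4 (18.2 to 1.72 CPM). They also included Cyp26b1, which degrades retinoic acid (102 to 10.6 CPM), and the secreted phosphoprotein gene Spp1 (33.7 to 4.19 CPM). Gbp2b also met the rule (-7.24 ± 1.9, SE), but it has near-identical paralogs and is uncertain.

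**Figure D4:**
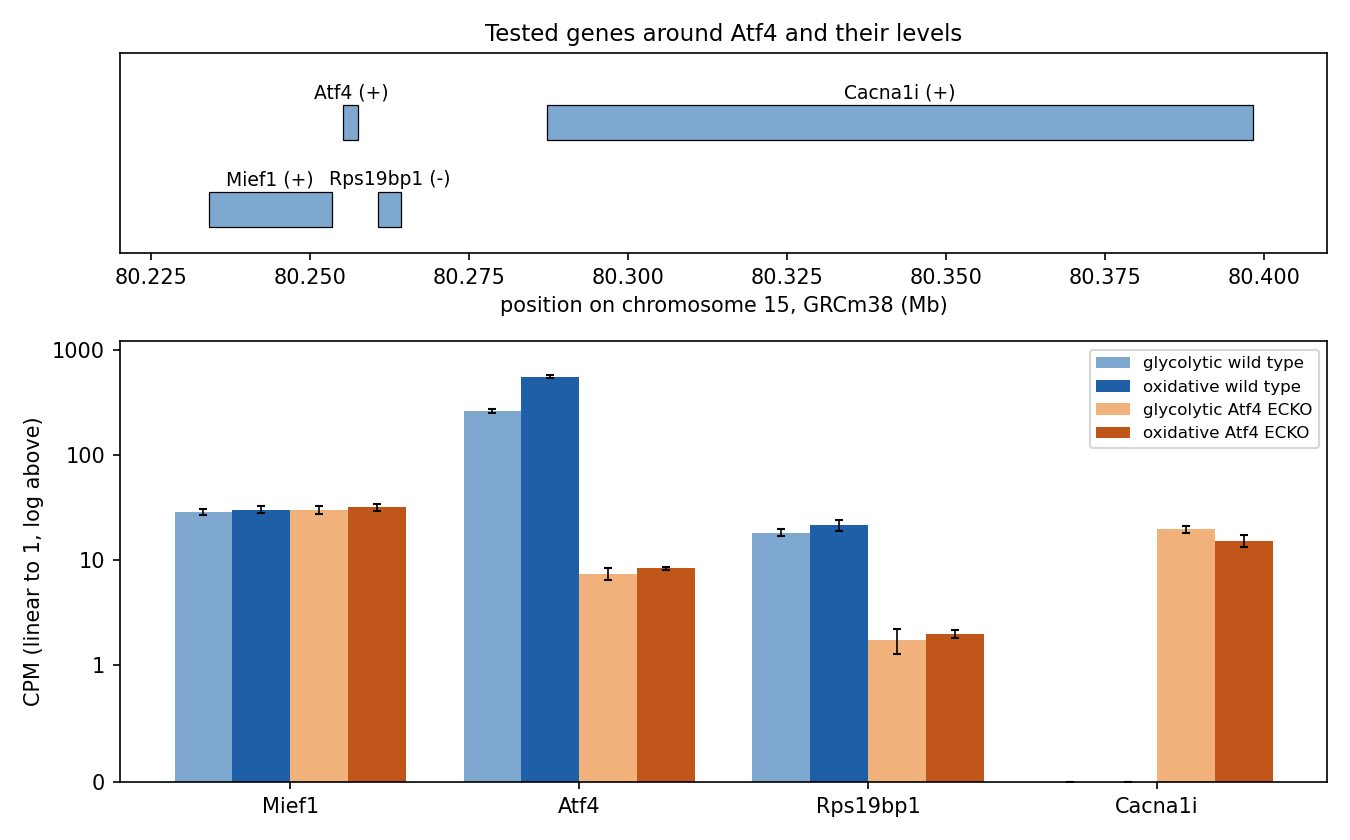
Map of the genes around Atf4 on chromosome 15 (upper panel) and mean levels with SD in CPM (vertical axis, lower panel) of Atf4 and its tested neighbours in the 4 groups. Rps19bp1 (80260615 to 80264315) is lower and Cacna1i (80287238 to 80398279) higher in ECKO of both muscles, while Mief1 (80234018 to 80253371) did not pass (adjusted p = 0.46 and 0.47).

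In total 4054 genes differed between glycolytic ECKO and wild type (edgeR, adjusted p below 0.05), 1939 higher and 2115 lower in ECKO, 363 and 203 of them at least 2-fold. Of 34 lists, 21 passed with the preset correlation and 8 of these also with an estimated one. All wild type libraries carried Y-linked RNA here and all ECKO libraries lacked it, so sex and genotype coincide. With the Y-linked share as a covariate 2139 genes were called. The amino acid synthesis list kept a mean of -1.60 on the voom scale (camera adjusted p = 3e-06), or -1.76 by edgeR. With it the amino acid transporters (mean -0.20, adjusted p = 0.81), tRNA synthetases (-0.19, 0.12), stress regulators (-0.35, 0.45), oxidative stress genes (-0.34, 0.12), venous markers (-0.30, 0.064) and fibre genes (0.33, 0.54) no longer passed. Pericyte, fibroblast and immune genes turned to -0.61, -2.53 and 0.68, and sprouting genes passed with 0.84. With immune genes as a covariate 2635 genes were called, and the transporters and stress regulators no longer passed (means -0.36 and -0.34, adjusted p = 0.23 and 0.065), nor did the immune list (mean -0.06, adjusted p = 0.84). Fibroblast and pericyte genes turned to -0.36 and -0.03, and oxidative stress and sprouting genes passed with -0.39 and 0.60. Muscle fibre genes as a covariate left 1716 genes called, the pericyte and fibroblast lists turned to -0.17 and -0.84, and the fibre list no longer passed (mean 0.12, adjusted p = 0.35).

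Between the muscles of Atf4 ECKO mice, the amino acid synthesis list did not differ by its test. Of 16 members 0 rose and 1 fell (1 called adjusted over the list alone, mean log2 fold change 0.25, camera adjusted p = 0.49). That member, Asns, was lower in oxidative muscle (31.3 against 39.4 CPM, -0.33 ± 0.055, SE, n = 5 per group). Stress regulators rose in 3 of 18 members and fell in 3 (6 called adjusted over the list alone, camera adjusted p = 0.88), and Gdf15 was lower in oxidative muscle (-1.22 ± 0.082). Venous markers fell in 7 of 9 members in oxidative muscle (mean -0.66, 7 called adjusted over the list alone, camera adjusted p = 2.3e-10, and 0.00011 estimated). Slco2a1, a prostaglandin transporter gene (-0.89 ± 0.083), Selp (-0.87 ± 0.063) and Plvap (-1.07 ± 0.045) were lower. Interferon response genes rose in 13 of 17 members and fell in 1 (mean 0.30, 14 called adjusted over the list alone, camera adjusted p = 9.8e-10, and 0.013 estimated). The antiviral Rsad2 (0.78 ± 0.07) and the regulator Irf7 (0.65 ± 0.078) were among them. Immediate early genes rose in 18 of 26 members and fell in 3 (mean 0.46, 21 called adjusted over the list alone, camera adjusted p = 9.8e-10 but adjusted p = 0.062 with an estimated correlation). Fosb rose by 1.07 ± 0.1 and Fos by 0.98 ± 0.075. Tagln (-1.91 ± 0.13), Acta2 (-1.50 ± 0.092) and Ankrd1 (-2.08 ± 0.16) were lower in oxidative muscle. The pericyte and smooth muscle list fell in 6 of 13 members and rose in 1 (mean -0.56, 9 called adjusted over the list alone, camera adjusted p = 4e-05 but adjusted p = 0.16 with an estimated correlation). With the Y-linked share as a covariate it did not pass (mean -0.30, adjusted p = 0.055), with immune genes it turned to 0.02 and with fibre genes it passed at -1.26.

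Slow fibre genes rose in 7 of 10 members in oxidative ECKO (mean log2 fold change 2.46, 7 called adjusted over the list alone, camera adjusted p = 1e-09, and 0.013 estimated). Myl3 stood at 8.78 against 0.393 CPM. The immune list rose in 10 of 15 members and fell in 1 (13 called adjusted over the list alone, mean 1.55, camera adjusted p = 4e-05 but adjusted p = 0.14 with an estimated correlation). Lyz2 rose by 2.47 ± 0.16 (SE, n = 5 per group) and Ctss by 3.35 ± 0.32. Mitochondrially encoded genes rose in 12 of 13 members (mean 0.67, 13 called adjusted over the list alone, camera adjusted p = 1.8e-15 but adjusted p = 0.079 with an estimated correlation). In total 2571 genes differed between the muscles in ECKO (edgeR, adjusted p below 0.05), 1161 higher and 1410 lower in oxidative muscle, 182 and 120 of them at least 2-fold. Of 34 lists, 18 passed with the preset correlation and 3 of these also with an estimated one. Oxidative ECKO libraries 4 and 5 match the glycolytic ECKO libraries in sex but not in fibroblast genes (4.66 and 4.7 against 3.33 to 3.47 mean log2 CPM). With these libraries alone, 2213 genes were called and the pericyte list no longer passed (mean -0.27, adjusted p = 0.1). The immune list and mitochondrially encoded genes then had means of 0.98 and 0.37, and 1.00 and 0.38 with the Y-linked share. Fibre or immune genes as a covariate gave 1174 and 1402 genes, with mitochondrially encoded genes at 1.19 and 0.20, and the immune list did not pass with its own covariate (mean 0.20, adjusted p = 0.42).

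The interaction tests whether the difference between ECKO and wild type depends on the muscle, and a negative value means a stronger fall or weaker rise in oxidative muscle. It equals the muscle difference in ECKO less that in wild type. The interaction of amino acid synthesis was negative in 13 of 16 members and positive in 0 (mean log2 value -1.37, 14 called adjusted over the list alone), and that of the transporters in 10 of 15 and 0 (median -1.10, 10 called adjusted over the list alone). For the tRNA synthetases it was negative in 13 of 20 and 1 (mean -0.63, 16 called adjusted over the list alone) and for stress regulators in 13 of 18 and 1 (mean -1.36, 17 called adjusted over the list alone). Gdf15 had -3.84 ± 0.11 (SE, n = 5 per group), since it fell in oxidative muscle and stood at 52.6 CPM in glycolytic ECKO against 29.8 CPM in wild type. Ppp1r15a had -1.89 ± 0.065, Atf3 -1.77 ± 0.13, Mthfd2 -1.92 ± 0.15, Asns -1.59 ± 0.071 and Rars -1.58 ± 0.086. Camera adjusted p was 4.6e-12, 1.6e-08, 1.2e-13 and 1.6e-13 for these lists, and 0.0034, 0.0061, 0.0053 and 0.00033 with an estimated correlation. In the oxidative stress list 7 of 11 members were negative and 0 positive (mean -0.84, 9 called adjusted over the list alone, camera adjusted p = 4.3e-06 but adjusted p = 0.069 with an estimated correlation). Hmox1 had -3.81 ± 0.12. In the endothelial activation list 7 of 9 were negative (mean -1.11, 8 called adjusted over the list alone, camera adjusted p = 9.8e-06, and 0.028 estimated). Cxcl1 had -2.28 ± 0.14.

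Cholesterol synthesis had a positive interaction in 12 of 19 members and a negative one in 0 (mean log2 value 0.57, 13 called adjusted over the list alone, camera adjusted p = 3.2e-08, and 0.00033 estimated). Idi1 had 1.04 ± 0.15 (SE, n = 5 per group). Interferon response genes were positive in 14 of 17 members (mean 0.50, 16 called adjusted over the list alone, camera adjusted p = 5.3e-12, and 0.0034 estimated). Gbp2, a GTPase gene with paralogs (0.84 ± 0.075), and Oasl2 (0.72 ± 0.093) were among them. Negative interactions were large for Gpnmb (-4.74 ± 0.29), Ankrd1 (-4.45 ± 0.24), Pmaip1 (-3.70 ± 0.22), the vasodilator peptide gene Adm (-1.80 ± 0.095), Fn1 (-1.92 ± 0.12) and Acta2 (-1.69 ± 0.13). Positive ones were large for the protease gene Adamts4 (2.30 ± 0.31) and the neuropeptide gene Nmb (1.83 ± 0.23). The immune list was negative in 6 of 15 members and positive in 1 (10 called adjusted over the list alone, mean -1.77, camera adjusted p = 0.00011 but adjusted p = 0.14 with an estimated correlation). Lyz2 had -1.81 ± 0.23. In total 3163 genes had an interaction (edgeR, adjusted p below 0.05), 1417 positive and 1746 negative. Of 34 lists, 21 passed with the preset correlation and 11 of these also with an estimated one. With the level of immune genes as a covariate 1689 genes were called, 925 of them among the 3163, and the immune list turned to 0.12. Transporters, tRNA synthetases and oxidative stress genes passed with -0.39, -0.40 and -0.43. With oxidative ECKO libraries 4 and 5 alone, where sex differs alike in both muscles, 3159 were called. These libraries held more fibroblast RNA than the glycolytic ECKO libraries, so RNA of other cells is not matched.

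Across the 13971 genes, which are not independent replicates, the log2 effects of genotype in the muscles had a Pearson correlation of 0.393 and a Spearman correlation of 0.284, with no libraries in common. Both effects were called higher for 560 genes and lower for 872, where independent lists of these sizes would share 282 and 369. They were called in opposite directions for 512 (646 for independent lists). Sex-specific RNA and Cre also differed between the genotypes in both muscles, so the shared part cannot be assigned to the deletion alone. The muscle differences in the genotypes had a Pearson correlation of 0.420 and a Spearman correlation of 0.158. Of the genes, 405 were higher and 385 lower in oxidative muscle of both genotypes (191 and 225 for independent lists), and 566 were opposite (417). Of the 629 genes at least 2-fold higher in oxidative wild type, 169 were also called higher in oxidative ECKO than glycolytic ECKO, 64 were called lower and 396 were not called. Their median log2 fold change was 1.60 in wild type and 0.42 in ECKO. Of the 121 genes at least 2-fold lower in oxidative wild type, 45 were also called lower in ECKO, 3 were called higher and 73 were not called. Their medians were -1.24 and -0.49. Both sets were chosen by their fold in wild type, which by itself makes the wild type median the larger.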

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

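The tests of explanations in this part, and the other splits of the libraries, were chosen after the results they concern had been seen.

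The difference between ECKO and wild type depended on the muscle for 3163 genes and for 21 gene lists, of which 11 also passed with an estimated correlation. Amino acid synthesis genes such as Asns fell more in oxidative muscle, Gdf15 fell there and rose in glycolytic muscle, and cholesterol synthesis genes such as Idi1 fell in glycolytic muscle, while their list did not pass its test in oxidative muscle (camera adjusted p = 0.79). The muscle difference of these lists had means of 1.61 and -0.57 in wild type but 0.25 and 0.00 in ECKO (camera adjusted p = 0.49 and 0.87). For both lists the interaction therefore mainly restates the wild type difference between the muscles. From the 31752 splits that exchange libraries within the groups compared, 100 were drawn. Only the real one, 1 split, reached 3163 genes and the highest other gave 7. In a mixed split the real group difference adds to the spread, which by itself keeps the count low. The libraries may also be technical, so these splits cannot exclude chance differences between animals. Splits say nothing about sex or RNA of other cells. With the level of immune genes as a covariate 1689 genes were called, 925 of them among the 3163, and with oxidative ECKO libraries 4 and 5 alone, where sex differs alike in both muscles, 3159 were called, of which 2422 were shared. The amino acid synthesis list passed in both (mean -1.03 and -1.33), and what part of the other interactions is due to the deletion stays open. Libraries 4 and 5 also held more fibroblast RNA than the glycolytic ECKO libraries. Splits of the compared libraries, 100 of 126 each time, gave the same pattern in the other comparisons, with the same limits. In each, 1 split, the real one, was as large. Fits of the compared groups alone gave 4577 genes against a highest other of 0 for the muscles in wild type, and 3919 against 31 for ECKO against wild type in oxidative muscle. They gave 4553 against 1 for ECKO against wild type in glycolytic muscle and 2214 against 1 for the muscles in ECKO.

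Xist, which the comparisons did not set out to use, stood at 61.4 CPM on average in glycolytic ECKO and 47.6 CPM in oxidative ECKO, against at most 0.274 CPM in wild type. Libraries 1, 2 and 3 of oxidative ECKO held Y-linked RNA as well, which needs RNA of more than 1 animal in a library or a mixture made later. The labels give no sex.

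In some groups of 5 libraries, 1 library stood apart from the other 4. Cacna1i was 18.8 CPM in oxidative ECKO library 1 against 13.6 to 15.1 CPM in the others. Amino acid transporters had a mean log2 CPM of 4.25 in glycolytic wild type library 2 (4.09 to 4.12 in the others), and basement membrane genes 8.09 in glycolytic ECKO library 3 (8.04 to 8.05). Capillary markers had 9.44 in glycolytic wild type library 5 (9.49 to 9.51), and pericyte and smooth muscle genes 3.91 in oxidative wild type library 4 (4.34 to 4.44). These are 5 of 190 groups over 48 measures, and chance alone marks about 1 in 20 groups.

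The loss of amino acid synthesis enzymes such as Asns in ECKO coincides with a change of sex, so sex was set against the deletion. In the oxidative ECKO libraries with Y-linked RNA, male cells at the wild type level would leave at least 28.2% to 57.5% of the list's level. The upper quartile over the 15 of 16 members called lower in this comparison was at most 19%. For these members that argues against sex as the cause there. The remaining member rose and was left out. In glycolytic muscle the list's mean moved by edgeR from -1.85 to -1.76 with the Y-linked share as a covariate. The SE over 16 members was 0.39 and the upper quartile -0.80. These values argue against sex as the whole cause if sex acts alike in the groups. The fibroblast list went from 1.13 (edgeR) to -2.53 (voom) and the immune list from -1.20 (edgeR) to 0.68 (voom). Those moves mix scales, so their sizes are not directly comparable with that of the amino acid list. The covariate's slope rests on the oxidative ECKO libraries, and the highest Y-linked share in glycolytic ECKO was 1.62%. A part due to sex, or an effect of sex in glycolytic muscle alone, thus cannot be told apart from the deletion. Oxidative ECKO libraries 1 and 5 held Y-linked shares of 56.6% and 0.961%, with fibroblast genes at 2.2 and 4.7 and immune genes at 1.19 and 0.14 mean log2 CPM. Changes of lists under this covariate can therefore follow RNA of other cells as well as sex. Loss of Atf4 in the endothelium is the biological explanation that the design offers, with a part due to sex still open. The wild type mice were without Cre, so an effect of Cre itself cannot be told apart from the deletion either.

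The higher Atf4 and amino acid synthesis genes in oxidative wild type endothelium came with more immune and fibre RNA, although the sort excluded CD45-positive cells. RNA from cells outside the deletion would keep in ECKO the share of the excess that their own genes kept. Immune genes (Lyz2 most abundant) kept a median of 8.54% (quartiles 7.27% to 9.31%) and fibre genes (Acta1 most abundant) 78.9% (67% to 126%). The amino acid list kept 0.177% (-0.678% to 1.42%) and Atf4 0.312% of 292 CPM. These values argue against fibres as the main source. For immune cells they do so only if all such cells changed alike in ECKO. The immune excess was itself mostly lost there, and single immune genes ranged from -18.7% to 22.1%, which includes the amino acid median. The immune and fibre lists share 0 genes with another list, but all their tested members had counts in endothelial libraries. Stress during isolation that differs between the muscles cannot be told apart from a difference within the animal, since isolation was not varied and immediate early genes were also higher in oxidative ECKO (mean log2 fold change 0.46, SE 0.099 over 26 members). A state of oxidative muscle endothelium that needs Atf4 may explain the pattern, with isolation stress and a part from immune cells still open.

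Rps19bp1 was lower and Cacna1i and Esr1 were higher in ECKO of both muscles. Sex would leave Rps19bp1 at 28.2% or more of wild type in the oxidative ECKO libraries with Y-linked RNA, where it was at most 10.2%, and it would lower Cacna1i and Esr1 there below the libraries without such RNA, where they were at least 103% and 122%, which argues against sex. Of the 3 tested genes within 50 kb of Atf4, 2 were among the 18 of 13970 genes changed at least 8-fold in both muscles (exact hypergeometric p = 4.7e-06), but the window and the fold were chosen after these genes had been seen, so chance placement stays open. A candidate explanation is that the altered Atf4 locus changes transcription of its neighbours. Esr1 lies on another chromosome, and reads from a Cre fused to an estrogen receptor may add to it, which was not tested because the transgene's sequence was not used here.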

How the results depend on the processing

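The covariate for immune genes, the choice of oxidative ECKO libraries by Y-linked RNA, that of oxidative wild type libraries by fibroblast RNA, the restriction to autosomes, the Y-linked share as a covariate on lists and leaving out a library on lists were chosen after seeing the data, and the other alternatives were planned. List values here are means on the voom scale. The cause of the changes below was not tested. In a fit with a covariate both effects share its slope, whose error enters both, so the correlations across genes in such fits do not show agreement. A list is counted as reversed by the direction of its camera test, which sets its genes against the other genes.

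RLE factors, no filter, DESeq2 and the length offset kept the counts of called genes within 1.5 times of the reported ones. With them all 271 results for named genes, each a gene in a comparison where it was called, kept direction and call. Atf4, Asns and Mthfd2 were among these genes. With limma-voom 268 results kept both and 3 lost the call. Most of these genes were picked for large changes or small adjusted p, which by itself makes a kept call likely. With fry 104 of 108 list results passed, and with an estimated correlation 49 did and 59 did not. Of the 108 list results, 70 kept their call with the fibre covariate, 76 with the Y-linked share and 63 with the immune covariate, 30, 23 and 25 lost it, and 8, 9 and 20 reversed. These include the fibre and immune lists with their own level as the covariate, whose change it takes out by construction. Of the results for named genes, 257, 257 and 209 kept it, 12, 12 and 52 lost it, and 2, 2 and 10 reversed. Autosomal and mitochondrial genes alone left 270 of 270 calls, and the 3 oxidative wild type libraries with less fibroblast RNA 176 of 176.

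With the level of muscle fibre genes as a covariate, the called genes numbered 1259 between the muscles in wild type, 1716 for ECKO in glycolytic muscle and 1174 between the muscles in ECKO, and the correlations across genes were 0.490 (genotype effects) and 0.723 (muscle differences). Between the muscles in wild type this covariate reversed chaperones (0.056), capillary markers (0.141) and fibroblast genes (-1.72, with Col1a1 at -2.25 and Dcn at -1.23). It also reversed pericyte genes (-0.169) and fibroblast genes (-0.838) for ECKO in glycolytic muscle and the cell cycle between the muscles in ECKO (-0.990). For immediate early genes in glycolytic ECKO (-0.079) and the fibroblast interaction (-0.005) the mean kept its sign and came closer to 0, the direction of the test turned and the call was lost.

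With the Y-linked share as a covariate, ECKO and wild type differed at 2643 genes in oxidative and 2139 in glycolytic muscle, and the correlations were 0.750 and 0.336. It reversed nuclear oxidative phosphorylation (0.003), fibre (-0.026) and pericyte genes (-0.446) in oxidative muscle. In glycolytic muscle it reversed chaperones (0.078), the cell cycle (0.127), nuclear oxidative phosphorylation (0.073), pericyte (-0.614), fibroblast (-2.53) and immune genes (0.681), Cnn1 (-0.858) and Gbp2b (2.04). With oxidative ECKO libraries 4 and 5 alone, Gbp2b reversed between the muscles in ECKO (-1.65) and in the interaction (-2.49). Of the 108 list results 101 kept their call with libraries 4 and 5 alone, and 101 with libraries 1, 2 and 3 alone. Each choice lost 7, with the same direction.

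With immune genes as a covariate, 1140, 1380, 2635, 1402 and 1689 genes were called (muscles in wild type, ECKO in oxidative and in glycolytic muscle, muscles in ECKO, interaction), and the correlations were 0.640 and 0.751. Between the muscles in wild type it reversed sprouting (-0.232), fatty acid (0.323), oxidative stress (-0.132) and pericyte genes (1.04), and Slc7a11 (-0.508), Ephb4 (0.160), Kirrel3 (0.362), Npr3 (0.229), Penk (3.78) and Pgf (-0.523). For ECKO in oxidative muscle it reversed nuclear oxidative phosphorylation (0.094), mitochondrial (0.297), fibre (-0.319), slow fibre (-0.392), fast fibre (-0.360), pericyte (-1.06) and immune genes (0.053), and mt-Nd1 (0.229), mt-Atp6 (0.150), Lyz2 (0.477) and Tyrobp (0.184). It reversed the cell cycle (0.018), pericyte (-0.034) and fibroblast genes (-0.361) for ECKO in glycolytic muscle, the cell cycle (-0.407) and pericyte genes (0.021) between the muscles in ECKO, and the mitochondrial (0.024) and immune (0.116) interactions. For capillary markers between the muscles in wild type (-0.046) and for ECKO in oxidative muscle (0.185) the mean kept its sign, the direction of the test turned and the call was lost.

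With limma-voom the correlation of muscle differences was 0.350. Fits of the compared groups alone gave 0.436 for genotype effects and 0.333 for muscle differences.

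The labels do not say whether the replicate numbers pair the libraries. Libraries of the same number correlated at -0.35 to 0.19 after removal of group means, which neither shows pairing nor excludes it. With the number as a block, 4388, 4332, 3970, 2440 and 3064 genes were called in the same order of comparisons.

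Leaving out 1 library at a time gave 4071 to 4648 genes between the muscles in wild type, 4058 to 4507 for ECKO in oxidative and 3553 to 4170 in glycolytic muscle. It gave 2159 to 2617 between the muscles in ECKO, 2927 to 3219 in the interaction, and correlations of 0.376 to 0.404 and 0.389 to 0.422. All 5420 results for named genes and 2139 of 2160 for lists kept their call, and 21 list results lost it. These were hypoxia genes in 5 fits (0.447 to 0.477), fatty acid genes in 4 (-0.072 to -0.066) and capillary markers in 1 (without oxidative wild type library 5, -0.114) between the muscles in wild type, and fatty acid genes in 1 between the muscles in ECKO (without oxidative ECKO library 5, 0.064). The others were endothelial activation for ECKO in oxidative muscle (without oxidative ECKO library 5, -0.845) and, in the interaction, fibre genes in 8 fits (-0.519 to -0.432) and fibroblast genes in 1 (without oxidative ECKO library 1, -0.897).

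Depth limits genes with few counts: 42374 genes were summed and 13971 had enough counts to test. Simulated 1.5-fold interactions were found for 42.4% of genes, so small differences in the effect of Atf4 go uncalled.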

Other observations

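The genes below were chosen after their values had been seen.

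Tnfsf18, the ligand of the T cell receptor GITR, stood at 9.81 CPM ± 1.75 (SD, n = 5) in glycolytic and 9.45 CPM ± 2.11 in oxidative wild type, and at 0.409 and 0.348 CPM in ECKO. Tnfsf4, the ligand of the T cell receptor OX40, stood at 0.659 and 1.12 CPM in wild type, at 0 counts in glycolytic ECKO and at 0.0242 CPM in oxidative ECKO (edgeR adjusted p = 2.7e-05 and 1.7e-06). Cyp26b1, which degrades retinoic acid, stood at 102 and 79.4 CPM in wild type and at 10.6 and 12.9 CPM in ECKO (log2 fold change -3.26 ± 0.17 and -2.63 ± 0.16, SE, edgeR adjusted p = 6.1e-14 and 6.5e-13). With the Y-linked share as a covariate, Cyp26b1 and Tnfsf18 stayed called in both muscles and Tnfsf4 did not (adjusted p = 0.33 and 0.25). With immune genes as a covariate, the calls of Tnfsf18 and Tnfsf4 in oxidative muscle were lost (adjusted p = 0.13 and 0.94).

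Atf3 in oxidative wild type was 367 to 381 CPM in libraries 1, 2 and 4 and 266 and 249 CPM in libraries 3 and 5. Col1a1 was 24.8 to 31 CPM in libraries 1, 2 and 4 and 77.6 and 90.6 CPM in libraries 3 and 5.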
